A study of Homo sapiens with 36 samples.

How the data were processed

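The series profiled mRNA and its polysome loading in MDA-MB-231, a human triple-negative breast cancer cell line. Cells carried a CRISPR interference construct that targeted either eGFP or the isoleucine tRNA with the GAU anticodon, and an overexpression construct that was either a control or the isoleucine tRNA with the UAU anticodon. The 4 lines are called control, UAU (overexpression alone), GAUi (CRISPR interference alone) and isoswitch (both changes). Per the labels, cells were treated with 100 ug/mL cycloheximide for 5 minutes before lysis and polysome fractionation. Each line gave total RNA, a low-translating fraction holding monosomes and the first polysome peak, and a high-translating fraction holding heavier polysomes. With 3 replicates (A, B and C) of each of 12 groups, there were 36 libraries, made from 500 ng RNA with the Lexogen QuantSeq 3' kit, which sequences the 3' ends of polyadenylated RNA.

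The files deposited for each library held raw counts per gene symbol, with no normalization. The submitters' processing notes name STAR, featureCounts, DESeq2 and the human genome build hg38. Tool versions, the gene annotation and the strand setting of the counting are not given in the sources used here. Of 26485 symbols, 21325 had a count in at least 1 library, and 23758 matched a symbol of the RefSeq annotation of GRCh38.p14, from which gene positions were taken. Library totals ran from 5192464 to 8974001 counts. Levels are given in CPM, counts scaled to a common library total with TMM factors over all 36 libraries, as mean ± SD over 3 libraries. The reads carry no molecular identifiers that were used here, so counting error understates the error of a value, and the tests rest on the spread between replicates. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples.

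Counts were tested with the edgeR quasi-likelihood test (edgeR 4.0.16 in R 4.3.3; glmQLFit and glmQLFTest), after filterByExpr on the groups and TMM scaling, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, with no fold minimum. SE is the log2 fold change divided by the square root of its F statistic. The 4 lines of a fraction shared a fit of 12 libraries, the comparison of fractions in control cells used its 9 libraries, and the high-to-total ratio was the difference between high fraction and total RNA in a line minus that difference in control, fitted over 24 libraries. An interaction was the effect of UAU overexpression in GAUi cells minus its effect in eGFP cells. The low-fraction comparisons of the UAU and GAUi lines, the interaction in the high fraction and the UAU effects within GAUi cells were added after the values were seen.

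The other comparisons of gene counts, the members of the gene lists and the rule for named genes were fixed before the data were examined. List tests were planned only for the comparison of fractions and for isoswitch against control in total RNA, high fraction and high-to-total ratio. All other list tests, among them those of UAU, GAUi, the low fraction and the interactions, were not planned. The rule took, for the comparison of fractions and for isoswitch against control in total RNA, high fraction and high-to-total ratio, the 10 highest and 10 lowest log2 fold changes among called genes with an average log2 CPM of at least 3 and no overlap between the replicates compared, and 4 of each for the other comparisons. For 3 libraries against 3, chance gives no overlap in 10% of genes. In the high-to-total ratio, overlap was judged on differences between libraries of the same letter, a pairing that no label gives. For interactions it was judged on the differences between every pair of replicates, where the 10% does not apply. Where no gene passed, the 5 smallest p were named. Up to 4 members of a list whose test passed were also named, by smallest p. Some genes that the rule took are not reported here. IARS was named by plan. The rule did not cover the neighbours of the tRNA genes, nor genes named under the flagged results to compare libraries. Any other gene named outside this rule is said to be chosen after the values were seen.

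There were 21 lists, of which 17 had at least 5 tested members and were tested with limma's camera (limma 3.58.1; inter-gene correlation preset to 0.01, log2 CPM with a prior count of 2), adjusted over the lists. The tests were repeated with an estimated correlation per list, and with fry. Mitochondrially encoded mRNAs were not analysed here, with 0 of 26 symbols matched. Lists of fibroblast, leukocyte and endothelial markers had 3, 2 and 4 tested members in total RNA, too few for camera, and are given as summed CPM. Shares of counts were compared with an exact two-sided permutation test, which for 3 libraries against 3 cannot go below p = 0.1.

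Simulated changes were set only in genes with a mean above 10 CPM, so recovery among less abundant genes was not tested. With 67 genes changed 2-fold in each comparison, the test recovered 67 for isoswitch against control in total RNA and 67 in the high fraction. It recovered 61 in the high-to-total ratio and 63 in the interaction in total RNA. For 67 genes changed 1.5-fold the numbers were 54, 56, 27 and 24. Of all calls in these 4 simulations 3.75% to 6.03% were false. Alternatives were the DESeq2 Wald test (DESeq2 1.42.0), RLE scaling, no count filter, a filter of 50 counts in 3 libraries, fits on the groups of a contrast alone or on all 36 libraries, the low fraction in place of total RNA, a replicate block, and leaving out each replicate in turn. Replicate pairs had log2 CPM correlations from 0.972 to 0.991 across genes. Their chi-square per degree of freedom ran from 8.53 to 23.8 in total RNA of GAUi, from 2.88 to 15.8 in the low fraction of control, and from 1.79 to 9.29 in the other 10 groups.

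The planned tests of isoleucine codon usage (the AUA share of isoleucine codons) need coding sequences and were not run. Coding length was not used here. The tRNAs themselves were not analysed here, and the library kit reads polyadenylated RNA.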

Results

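The data cover total RNA and fractions of low and high translation from 4 MDA-MB-231 lines: control, UAU, GAUi and isoswitch. Per library, total RNA had 6679340 to 8973050 counts (12 libraries), the low fraction 5310594 to 8234332 (12 libraries) and the high fraction 5192464 to 8974001 (12 libraries). Between 14783 and 16427 genes were detected per library. The 10 most abundant genes took 5.74% to 6.22% of the counts in total RNA, 9.03% to 9.79% in the low fraction and 6.13% to 7.83% in the high fraction.

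The targets were tRNAs, which these libraries do not read, so the change in tRNA level was not measured. The 3 annotated genes of the isoleucine tRNA with the GAU anticodon lie on chromosome X (GRCh38.p14), the first at 3838377 to 3838450, the last at 3915230 to 3915303. The pseudogene LOC389906 (X, 3817535 to 3843894) overlaps the first of them and was higher in GAUi than in control total RNA (log2 fold change 0.60, SE 0.18, adjusted p = 0.0415, edgeR quasi-likelihood test). Its log2 fold change was 0.22 in isoswitch (adjusted p = 0.649). PRKX (X, 3604340 to 3713649), a protein kinase gene and the nearest coding gene with enough counts, did not pass in GAUi (0.21, adjusted p = 0.367). IARS, the cytosolic isoleucyl-tRNA synthetase, had 59.7 ± 1.68 CPM (SD, n = 3) in control total RNA and passed the test in none of the comparisons. Its log2 fold change in total RNA was 0.08 in UAU, 0.33 in GAUi (adjusted p = 0.0766) and 0.26 in isoswitch (adjusted p = 0.256).

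What the gradient separated was examined first in control cells. Long non-coding RNAs, many of them snoRNA host transcripts that are not translated into stable proteins, lay mostly in the low fraction. Of 20 tested, 18 were lower in the high fraction and 1 was higher, with a median log2 fold change of -2.85. SNHG5 fell from 2545 ± 222 CPM in the low to 109.7 ± 2.19 CPM in the high fraction (SD, n = 3; log2 fold change -4.56, SE 0.09, adjusted p = 8.9e-14). SNHG25 (-5.05) and SNHG19 (-4.41) were also among the 10 lowest. So were MTRNR2L2, MTRNR2L8, RNU4ATAC, MIR1248 and SNORA81, whose reads are uncertain, since the first pair resemble mitochondrial rRNA and the others lie within other genes. At the other end, TAGLN2, an actin-binding protein, had 592 ± 111 CPM in the low and 3390 ± 390 CPM in the high fraction (log2 fold change 2.49, SE 0.13). TK1, the S phase thymidine kinase (2.44), and the antioxidant enzyme PRDX1 (2.35) were higher in the high fraction by similar amounts. ZBTB20 was the highest (2.54), but its log2 fold change against total RNA in place of the low fraction was -0.11.

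Among coding groups in the same comparison, endoplasmic reticulum chaperones were higher for 13 of 20 members and lower for 2. Examples were DNAJB11 (2.06) and calreticulin, CALR (1.82). Nuclear-encoded respiratory chain mRNAs went both ways, with 24 of 39 higher and 8 lower: NDUFB8 had a log2 fold change of 1.81 and UQCRH of -1.86. Glycolysis and hypoxia genes were higher for 14 of 23 and lower for 1, among them TPI1 (2.19) and ALDOA (1.63). Luminal epithelial markers were higher for 8 of 10 and lower for 1. Counts adjusted over the list alone were identical for these 5 lists. In all, 8094 of 12266 genes were called, 4021 higher and 4073 lower in the high fraction. Levels were scaled within each library, so these are changes in share between fractions, not in absolute amount. The scaling sets much of the even split between higher and lower genes. The camera test passed for the non-coding list (adjusted p = 7.84e-10), the chaperones (0.00817), the respiratory chain (0.00954), glycolysis and hypoxia (0.00954) and luminal markers (0.0251). None of these held with an estimated correlation: adjusted p = 0.154, adjusted p = 0.162, adjusted p = 0.311, adjusted p = 0.345 and adjusted p = 0.187 with an estimated correlation, in that order.

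Isoswitch cells carried both tRNA changes, the condition the series is named for. In their total RNA, S100A4, a calcium-binding protein associated with metastasis (chromosome 1, 153543621 to 153545806), fell from 842 ± 23.6 CPM in control to 283 ± 12.5 CPM (SD, n = 3; log2 fold change -1.58, SE 0.10, adjusted p = 2.91e-08). The lactonase PON2 fell from 20.3 ± 1.76 to 5.37 ± 0.533 CPM. The receptor GPRC5C (-1.75), IGFBP1 (-1.10) and the tight junction protein CLDN4 (-1.07) were lower as well. In the other direction, cadherin CDH11 rose from 2.65 ± 0.597 to 14.3 ± 1.51 CPM (2.41, SE 0.23, adjusted p = 3.36e-06). PTK7, a receptor of Wnt signalling (1.84), KRTAP2-3 (1.82), the Wnt inhibitor APCDD1L (0.95) and the keratin KRT81 (0.88) rose too. CD274, which encodes the immune checkpoint ligand PD-L1, rose from 8.07 ± 1.11 to 15.5 ± 2.12 CPM (0.93, SE 0.15, adjusted p = 0.00129). APCDD1L-AS1 (1.01) overlaps its sense gene, and the strand of counting is not given, so it is uncertain.

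Cholesterol synthesis was the gene group with the clearest change in isoswitch total RNA. Of 22 genes tested, 7 were lower and 0 higher; adjusted over the list alone, 11 were lower and 0 higher. INSIG1, which holds back the sterol-sensing transcription factors, fell from 294.4 ± 7.93 to 134 ± 3.95 CPM (log2 fold change -1.14, SE 0.08, adjusted p = 6.1e-08). The enzymes CYP51A1 (-0.73) and HMGCS1 (-0.66) fell. The list's median was -0.34 (camera adjusted p = 1.99e-10), and it held with an estimated correlation (adjusted p = 0.00532 with an estimated correlation). Immediate early genes were higher for 3 of 19 members, 10 when adjusted over the list alone, and lower for 0 in both (camera adjusted p = 3.14e-05; adjusted p = 0.135 with an estimated correlation). MYC rose from 15.3 ± 0.417 to 24.01 ± 1.32 CPM (0.65, adjusted p = 0.00701). The immediate early list was set up to follow handling and cycloheximide. Differences in handling at harvest therefore cannot be told apart from an effect of the line, here or in the fractions. Aminoacyl-tRNA synthetases had 2 of 20 higher, 4 adjusted over the list alone, and 0 lower (camera adjusted p = 0.0118; adjusted p = 0.0848 with an estimated correlation). TARS rose (0.32, adjusted p = 0.00772), but not without control A (adjusted p = 0.0601) or isoswitch B (adjusted p = 0.0639). Ribosomal protein genes (2 of 78 higher, 1 adjusted over the list alone) and glycolysis and hypoxia genes (1 of 23 higher, 2 adjusted over the list alone) passed camera with adjusted p = 0.0268 each. Their adjusted p = 0.631 and adjusted p = 0.517 with an estimated correlation.

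Across isoswitch total RNA, 500 of 12357 genes were called, 159 higher and 341 lower (edgeR quasi-likelihood test). The count without a library was 212 for control A, 233 for control B, 250 for control C, 268 for isoswitch A, 194 for isoswitch B and 218 for isoswitch C. Fitted on the control and isoswitch libraries alone, 1898 genes were called. The number of lists that passed, 5, was 2 without control A, 3 without control B and 3 without isoswitch B.

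**Figure D1:**
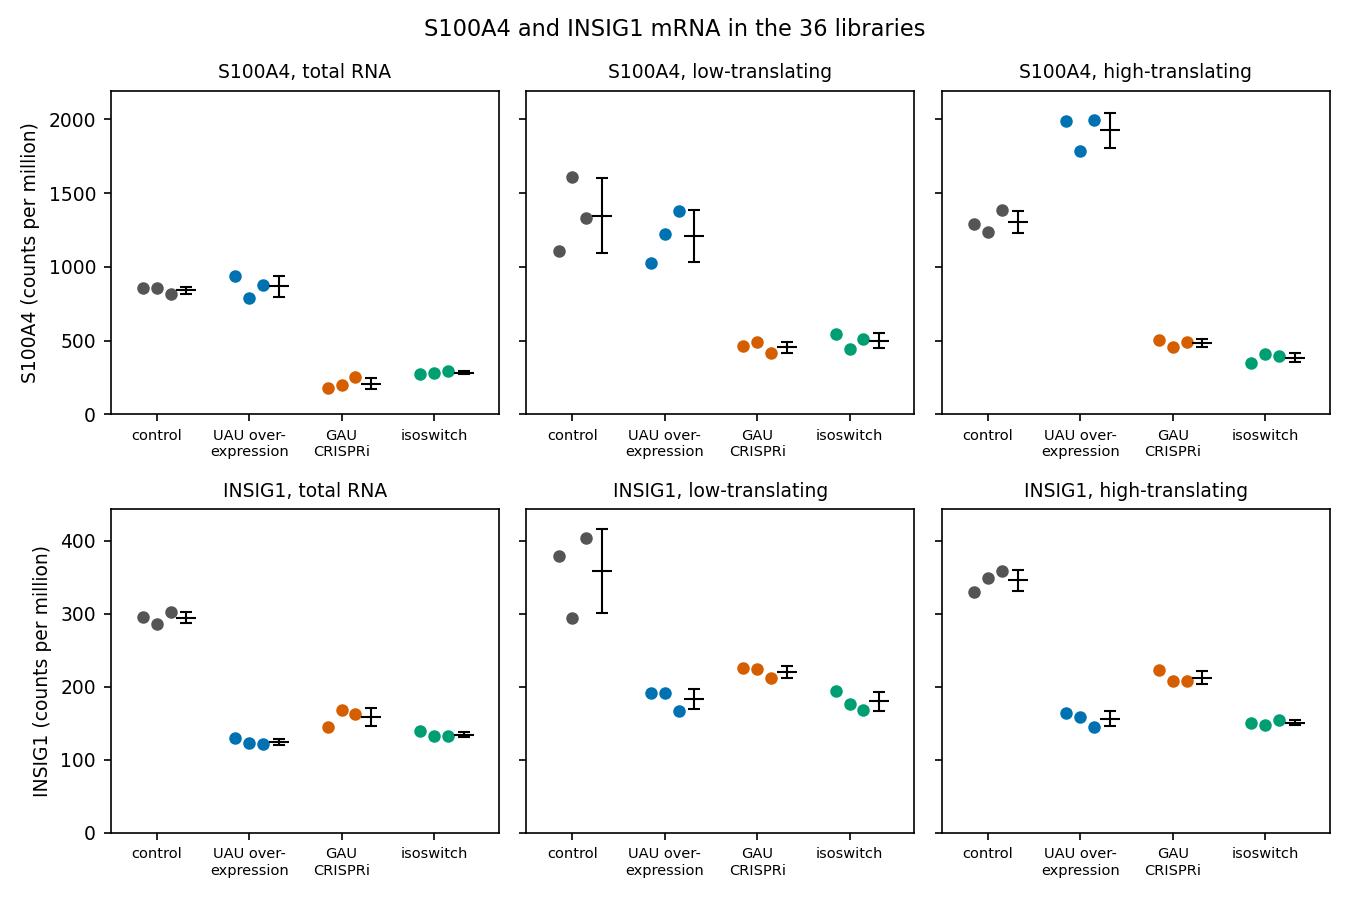
S100A4 (upper panels) and INSIG1 (lower panels) in CPM, by line, for total RNA, low and high fractions; points are libraries, and the bar beside them is the mean with SD (n = 3). Mean S100A4 in total RNA was 842 in control and 867 in UAU against 208 in GAUi and 283 in isoswitch, while mean INSIG1 was 294.4 in control and 124.8 to 158 in the other 3 lines.

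With UAU overexpression alone, sterol genes were among the strongest changes in total RNA. INSIG1 fell from 294.4 ± 7.93 to 124.8 ± 4.14 CPM (SD, n = 3; log2 fold change -1.22, SE 0.08, adjusted p = 3.82e-08). HMGCS1 changed by -0.96. Of the 22 cholesterol genes, 7 were lower and 0 higher; adjusted over the list alone, 12 were lower and 0 higher. The median was -0.35 (camera adjusted p = 2.39e-14; adjusted p = 0.00173 with an estimated correlation). PTGES, a prostaglandin E synthase (-1.10), and GPRC5C (-1.07) fell, and PKIA, an inhibitor of protein kinase A, rose (0.92, adjusted p = 0.00161). Mitotic genes (0 of 30 called; 0 higher and 3 lower adjusted over the list alone), interferon response genes (0 of 24, and 0 adjusted over the list alone) and non-coding RNAs (0 higher and 1 lower of 20; 2 lower adjusted over the list alone) passed camera towards lower levels. They had adjusted p = 0.576, adjusted p = 0.141 and adjusted p = 0.374 with an estimated correlation. In total 113 genes were called, 43 higher and 70 lower, but 916 in a fit on the control and UAU libraries alone and 201 by DESeq2. Without control A, B or C the count was 31, 25 or 33, and without UAU A, B or C it was 43, 29 or 31. The 4 lists that passed became 2 without UAU A.

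With GAU CRISPR interference alone, S100A4 in total RNA fell to 208 ± 38.0 CPM (log2 fold change -2.04, SE 0.10, adjusted p = 3.79e-10). DDIT4, an inhibitor of mTORC1 induced by stress, fell from 112 ± 5.87 to 34.9 ± 3.61 CPM (-1.70, SE 0.10, adjusted p = 4.25e-09), and GPRC5C fell (-1.81). KRTAP2-3 (2.09), CDH11 (2.03) and PTK7 (1.93) rose. Ribosomal protein mRNAs were higher for 26 of 78 genes and lower for 3; adjusted over the list alone, 38 and 3 (camera adjusted p = 3.72e-06; adjusted p = 0.139 with an estimated correlation). RPL28 rose from 371 ± 16.2 to 533 ± 41.6 CPM, and RPL19 by a log2 fold change of 0.46. Interferon response genes were lower for 9 of 24 and higher for 1; adjusted over the list alone, 11 and 2. BST2, which tethers virus particles, fell from 35.6 ± 0.904 to 17.8 ± 3.49 CPM, and IFIT2 changed by -0.98. The list had adjusted p = 0.018 with camera and adjusted p = 0.139 with an estimated correlation. Cholesterol genes were lower for 7 of 22 and higher for 0; adjusted over the list alone, 9 and 1 (camera adjusted p = 0.000311; adjusted p = 0.101 with an estimated correlation), with INSIG1 at -0.92. Aminoacyl-tRNA synthetases were higher for 3 of 20 and lower for 0; adjusted over the list alone, 8 and 0 (camera adjusted p = 0.0168; adjusted p = 0.101 with an estimated correlation).

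In GAUi total RNA 1248 genes were called, 541 higher and 707 lower. Fitted on the control and GAUi libraries alone the count was 329, so which of UAU and GAUi had more called genes depended on the libraries in the fit. Pairs of GAUi libraries had a chi-square per degree of freedom of 8.53 to 23.8, against 1.79 to 3.73 in the other 3 groups of total RNA. Without GAUi A the count was 2134, and without control A, B or C it was 622, 531 or 724.

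In the high fraction, the question was which mRNAs the modified cells kept on heavy polysomes. Isoswitch cells had less S100A4 there, at 383.5 ± 29.7 CPM against 1302 ± 74.5 CPM in control (SD, n = 3; log2 fold change -1.77, SE 0.08, adjusted p = 1.82e-14). PON2 changed by -2.33, GPRC5C by -1.97, IGFBP1 by -1.46 and INSIG1 by -1.20. HSPA1B, an inducible heat shock protein, changed by -1.24; its sequence is nearly identical to HSPA1A, so its reads are uncertain. KRTAP2-3 (1.86), KRT81 (1.00), APCDD1L (0.95), MYC (0.92) and CD274 (0.86) were higher. Immediate early genes were higher for 7 of 18 and lower for 0; adjusted over the list alone, 10 and 1 (camera adjusted p = 5.55e-05; adjusted p = 0.101 with an estimated correlation), with DUSP5 at 0.56 and JUN at 0.40. Cholesterol genes were lower for 8 of 22 and higher for 0; adjusted over the list alone, 11 and 0 (camera adjusted p = 5.82e-06; adjusted p = 0.101 with an estimated correlation). Long non-coding RNAs were lower for 10 of 19 and higher for 0; adjusted over the list alone, 11 and 0, among them MIR22HG (-0.74) and NEAT1 (-0.53). That list had camera adjusted p = 6.3e-06 and adjusted p = 0.402 with an estimated correlation. These RNAs lay mostly in the low fraction of control cells. Across genes, the isoswitch change in the high fraction had a Spearman correlation of -0.19 with low minus high fraction of GAUi cells. Over single pairs of libraries it ran from -0.25 to -0.08. Less light material carried into the isoswitch high fraction therefore cannot be told apart from a change of these RNAs. Glycolysis and hypoxia genes had 4 of 23 higher, 4 adjusted over the list alone, among them the mitophagy receptor BNIP3 (0.56), and 0 lower (camera adjusted p = 0.00219; adjusted p = 0.498 with an estimated correlation). Synthetases (4 of 20 higher, 4 adjusted over the list alone) and mitotic genes (2 of 30 higher, 1 adjusted over the list alone) passed camera with adjusted p = 0.0361 and adjusted p = 0.0252, and both had adjusted p = 0.576 with an estimated correlation.

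Among high-fraction genes, 1322 of 11979 were called in isoswitch, 440 higher and 882 lower. The count was 718 without control C and 651 without isoswitch A.

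UAU cells had more called genes in the high fraction than either other line, 3432 against 1322 in isoswitch and 1215 in GAUi. Called genes that changed at least 2-fold were similar in number, 87 in UAU, 83 in isoswitch and 89 in GAUi. In UAU cells mitotic mRNAs were lower for 20 of 30 genes and higher for 1 (21 and 1 adjusted over the list alone). Cyclin B1, CCNB1, fell from 324.5 ± 8.06 CPM in control to 184 ± 17.6 CPM (SD, n = 3; log2 fold change -0.81, SE 0.08, adjusted p = 3.16e-07). Replication genes were lower for 14 of 25 and higher for 1 (15 and 1 adjusted over the list alone), among them the licensing factor CDC6 (-0.74). Glycolytic GAPDH fell from 1905 ± 76.9 to 1048 ± 209 CPM, and its list had 9 of 23 lower and 4 higher (11 and 4 adjusted over the list alone). Endoplasmic reticulum chaperones had 10 of 20 lower and 3 higher (12 and 5 adjusted over the list alone), with CALR at -0.85. Cytosolic heat shock genes had 9 of 15 lower and 1 higher (10 and 1 adjusted over the list alone), with HSP90AA1 at -0.67. Translation factors had 15 of 32 lower and 4 higher (16 and 4 adjusted over the list alone), with EIF3B at -0.73. Synthetases had 8 of 20 lower and 0 higher (9 and 0 adjusted over the list alone), with DARS at -0.76. Metastasis genes had 8 of 23 lower and 0 higher (8 and 0 adjusted over the list alone), with CD44 at -0.69. S100A4, chosen here after the values were seen, was higher in this fraction (0.58, adjusted p = 1e-05).

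Among ribosomal protein and respiratory chain genes, more were higher than lower in UAU high fractions. Ribosomal protein genes were higher for 41 of 78 and lower for 4; adjusted over the list alone, 47 and 6. RPS12 rose from 1406 ± 121 to 2099 ± 47.9 CPM and RPL22 from 343 ± 10.5 to 500.3 ± 24.6 CPM. Respiratory chain genes were higher for 19 of 39 and lower for 8; adjusted over the list alone, 23 and 10, with NDUFA1 at 0.69 and COX6C at 0.75. Cholesterol genes were lower for 17 of 22 and higher for 0; adjusted over the list alone, 18 and 1, with INSIG1 at -1.14, IDI1 at -1.05 and a list median of -0.66. All 11 of these lists passed camera in UAU, with adjusted p from 2.53e-09 for cholesterol and 3.32e-08 for ribosomal proteins to 0.0292 for glycolysis and hypoxia. With an estimated correlation the cholesterol list held (adjusted p = 0.0288), and the other 10 did not (adjusted p = 0.223 to adjusted p = 0.352 with an estimated correlation). In total 3432 genes were called in the UAU high fraction, 1570 higher and 1862 lower.

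With GAU CRISPR interference alone, 46 of 78 ribosomal protein mRNAs were higher in the high fraction and 0 lower; adjusted over the list alone, 60 and 0. RPS29 rose from 4146 ± 106 to 5826 ± 351 CPM (SD, n = 3; log2 fold change 0.49, SE 0.08, adjusted p = 0.000119). Interferon response genes fell for 7 of 23 and rose for 0; adjusted over the list alone, 11 fell and 1 rose. IFIT2 fell from 9.21 ± 2.30 to 3.14 ± 0.206 CPM, and IFIT3 changed by -0.98. Cholesterol genes fell for 5 of 22 and rose for 0; adjusted over the list alone, 9 and 0, with INSIG1 at -0.70 and CYP51A1 at -0.77. PON2 (-2.15), GPRC5C (-1.76), IGFBP1 (-1.46) and S100A4 (-1.42, chosen here after the values were seen) were lower, as was CLDN4 (-1.20). MCM7, a subunit of the replicative helicase, fell (-0.88), and its list had 7 of 25 lower and 1 higher (8 and 1 adjusted over the list alone). HSPB1 (-0.75) and BAG3 (-0.63) fell in a heat shock list with 3 of 15 lower and 1 higher (5 and 1 adjusted over the list alone). The camera test passed for 10 lists. Interferon response (adjusted p = 0.0177 with an estimated correlation) and cholesterol (adjusted p = 0.0467 with an estimated correlation) held. Ribosomal proteins (adjusted p = 0.0885 with an estimated correlation), heat shock (adjusted p = 0.318 with an estimated correlation) and replication (adjusted p = 0.424 with an estimated correlation) did not. The other 5 lists, mitosis (1 higher and 2 lower; 1 and 3 adjusted over the list alone), synthetases (0 and 2; 0 and 2), respiratory chain (9 and 2; 12 and 5), metastasis (0 and 4; 0 and 4) and luminal markers (1 and 2; 2 and 5), had adjusted p = 0.421 to adjusted p = 0.424 with an estimated correlation.

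Over all genes in the GAUi high fraction, 1215 were called, 558 higher and 657 lower. Without control A or B the count was 569 or 724, and without GAUi A, B or C it was 563, 803 or 705. The 10 lists that passed became 3 without control A and 5 without GAUi A.

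**Figure D2:**
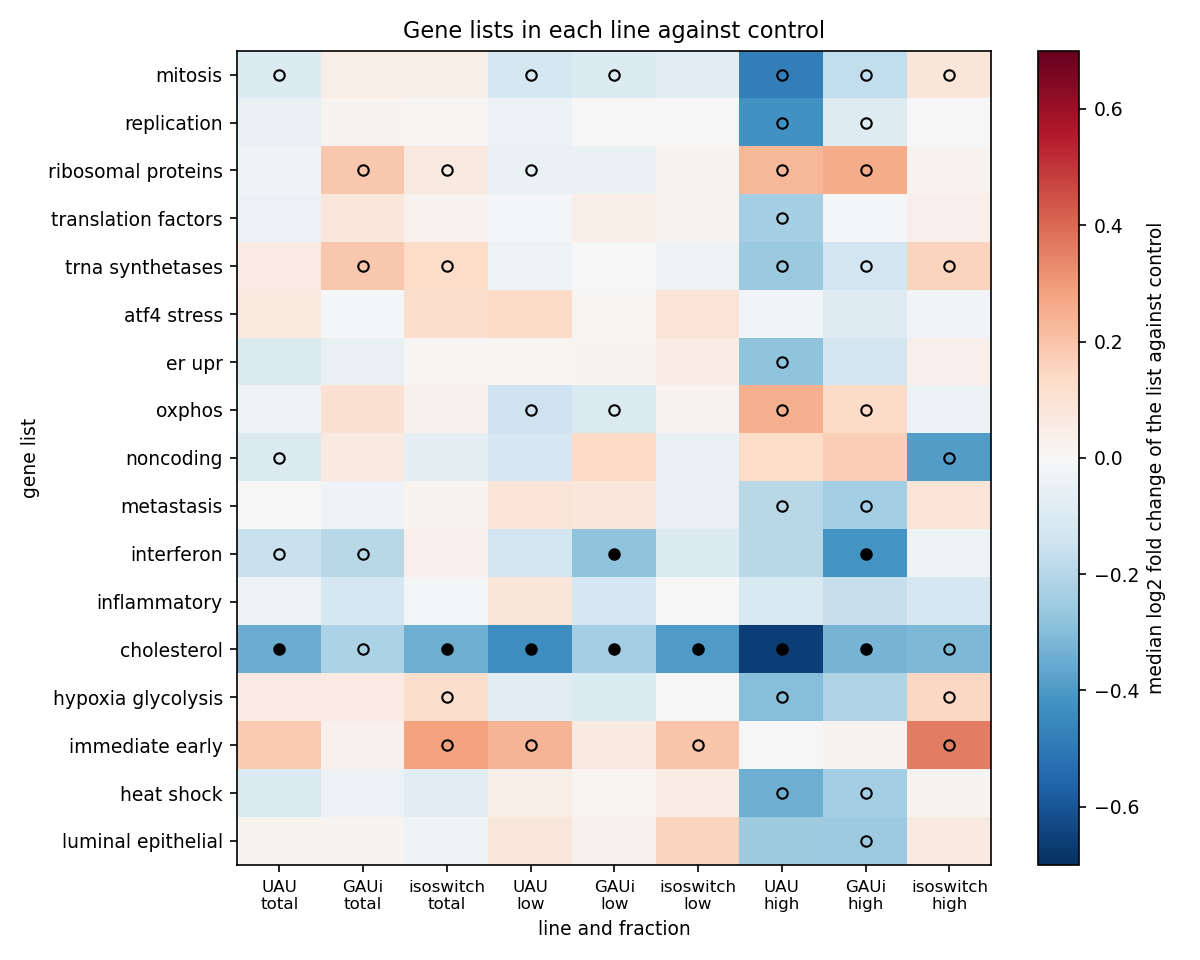
Median log2 fold change against control (colour) of each tested gene list (vertical axis) for 3 lines in 3 fractions (horizontal axis); circles mark lists that passed camera, filled where the call held with an estimated correlation. The cholesterol list had a negative median in every column, each against the shared control libraries of the fraction, with medians from -0.66 in the UAU high fraction to -0.22 in GAUi total RNA.

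The share of counts that fell in the 78 ribosomal protein genes was compared as well. For the high fraction it was 15.8% ± 0.326 in control and 15.7% ± 0.441 in isoswitch, against 17.45% ± 0.244 in UAU and 18.15% ± 0.350 in GAUi (SD, n = 3). By an exact two-sided permutation test against control the p was 0.1 for UAU, 0.1 for GAUi and 0.9 for isoswitch, where 0.1 is the smallest the design allows. In the low fraction, where ribosomal protein mRNAs took 18.5% to 19.2% in the 4 lines, the exact p was 0.5 for UAU, 0.4 for GAUi and 1 for isoswitch. In total RNA the share was 14.97% in control and 15.77% in GAUi, with an exact p of 0.1.

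**Figure D3:**
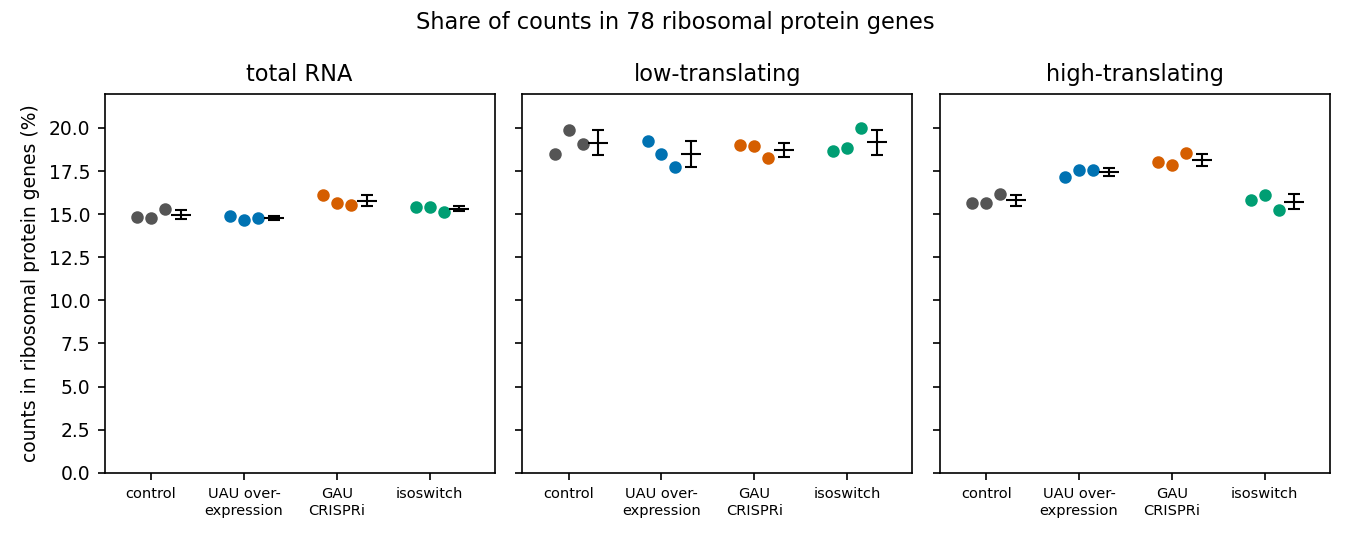
Percent of a library's counts in ribosomal protein genes, by line, in each fraction; points are libraries, and the bar beside them is the mean with SD (n = 3). In the high fraction UAU (17.16 to 17.59) and GAUi (17.87 to 18.55) lay above all libraries of control (15.62 to 16.18) and isoswitch (15.23 to 16.09).

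In the low fraction of isoswitch cells, the sterol change was present as well. INSIG1 fell from 358.5 ± 57.5 to 179.8 ± 13.3 CPM (SD, n = 3; log2 fold change -0.998, SE 0.11, adjusted p = 8.82e-05), and CYP51A1 changed by -0.71. Cholesterol genes were lower for 3 of 21 and higher for 0; adjusted over the list alone, 7 and 0 (camera adjusted p = 1.45e-08; adjusted p = 0.00253 with an estimated correlation). Immediate early genes were higher for 3 of 20 and lower for 0; adjusted over the list alone, 3 and 0 (camera adjusted p = 0.0134; adjusted p = 0.67 with an estimated correlation). The metallothionein MT1F fell from 14.8 ± 0.983 to 4.80 ± 1.56 CPM, PON2 from 26.2 ± 0.990 to 9.56 ± 0.985 CPM and PRKAR1B, a regulatory subunit of protein kinase A, by a log2 fold change of -1.52. The transcription factor HOXB9 rose (1.11, adjusted p = 0.00172). In total 321 of 12445 genes were called, 120 higher and 201 lower, and 105 in a fit on the control and isoswitch libraries alone. Control B of this fraction stood apart from control A and C, and the count was 675 without it. It was 173 without control C, 127 without isoswitch A and 174 without isoswitch C.

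Whether mRNAs changed their polysome loading beyond their total level was asked with the high-to-total ratio. In isoswitch cells no gene passed: 0 of 12540 by the edgeR quasi-likelihood test and 0 by DESeq2, with 648 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.518. Other settings gave a few genes: 15 in a fit on the control and isoswitch libraries alone (1 higher, 14 lower), 18 with no count filter (0 higher, 18 lower) and 1 against the low fraction in place of total RNA (higher). The genes with the smallest p, none of which passed, were the copper chaperone COX17 (log2 difference -0.74, SE 0.16), FAM69B (-0.58), the translation factor EIF5A (-0.60), DPM2 (-0.81) and SSNA1 (-0.64). On simulated data, with changes set only in genes above a minimum CPM, the same design recovered 61 of 67 genes changed 2-fold and 27 of 67 changed 1.5-fold. Recovery among less abundant genes was not tested. Long non-coding RNAs had a median of -0.29 with 0 of 20 called; adjusted over the list alone, 6 were lower and 0 higher, DANCR at -0.83 and ZFAS1 at -0.55 having the smallest p. That list passed camera (adjusted p = 2.18e-06), but not with an estimated correlation (adjusted p = 0.472 with an estimated correlation). Here too, less light material in the isoswitch high fraction cannot be told apart from a change of these RNAs. The number of lists that passed, 1, was 2 without control A and 3 without isoswitch B.

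In UAU cells members of 12 lists changed their high-to-total ratio, though no list held with an estimated correlation. RPS12 (log2 difference 0.91, SE 0.12, adjusted p = 2.75e-05), RPL22 (0.86) and RPL37A (0.60) rose in a list with 28 of 78 higher and 1 lower; adjusted over the list alone, 37 and 2. NDUFA1 (0.93) and COX6C (0.88) rose in a list with 12 of 39 higher and 3 lower (22 and 8 adjusted over the list alone). SNHG6 (0.78) rose with 5 of 20 non-coding RNAs, against 0 that fell (7 and 0 adjusted over the list alone). GAPDH (-0.83) and ENO1 (-0.75) fell in a list with 6 of 23 lower and 0 higher (7 and 2 adjusted over the list alone). RRM2, a subunit of ribonucleotide reductase (-0.81), DARS (-0.73), EIF2S1 (-0.56), vimentin VIM (-0.72) and CD44 (-0.67) fell. Outside the lists, GDF9 (1.36) and the cytochrome oxidase assembly factor PET100 (1.20) rose and the mitochondrial chaperone TRAP1 fell (-1.18). Lower members outnumbered higher ones among mitotic genes (7 and 0 of 30; 13 and 0 adjusted over the list alone), replication genes (6 and 0 of 25; 9 and 1), translation factors (8 and 0 of 32; 10 and 0), chaperones of the endoplasmic reticulum (6 and 0 of 20; 8 and 1), metastasis genes (5 and 0 of 27; 6 and 1), synthetases (2 and 0 of 20; 7 and 0), heat shock genes (2 and 1 of 15; 4 and 1) and luminal markers (2 and 0 of 10; 3 and 0). These 12 lists passed camera (ribosomal proteins, adjusted p = 4.86e-13), and none held (adjusted p = 0.129 to adjusted p = 0.217 with an estimated correlation). In all 918 genes were called, 448 higher and 470 lower, and 1447 in a fit on the control and UAU libraries alone. The count was 213 without control A, 241 without control B, 295 without UAU A and 281 without UAU B, and the 12 lists became 6 without UAU B. Against the low fraction in place of total RNA 833 genes passed, and 383 of them were among the 918.

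In GAUi cells 90 genes changed their high-to-total ratio, 28 higher and 62 lower, and no gene passed without control A or without control B. A fit on the control and GAUi libraries alone called 0 genes by the edgeR quasi-likelihood test (1853 at an unadjusted p under 0.05 in the fit of all 4 lines), and DESeq2 called 262. Against the low fraction in place of total RNA 25 genes passed, 25 higher and 0 lower, and 0 of them were among the 90. The glycolytic enzymes PKM (log2 difference -0.90, SE 0.16, adjusted p = 0.00721) and PGK1 (-0.55) and the RNA demethylase FTO (-1.20) fell. RPS14 rose (0.70, adjusted p = 0.0256) with 5 of 78 ribosomal protein genes, against 0 that fell (17 and 3 adjusted over the list alone). UBTD1 rose (1.00), but measured against the low fraction its value was -0.067, and that of PKM was 0.0035. HIST2H2AB (1.39) and HIST1H2BC (1.23) rose, with reads that related histone genes can share. Lists that passed camera with lower members were replication (3 of 25; 5 adjusted over the list alone), glycolysis and hypoxia (4 of 23; 8), heat shock (2 of 15; 2 lower and 1 higher) and synthetases (0 of 20; 4). In the mitosis list 0 of 30 genes were called, and 0 adjusted over the list alone. Mitosis and the ribosomal proteins passed camera too, and none of the 6 lists held (adjusted p = 0.21 to adjusted p = 0.507 with an estimated correlation). The count was 49, 136 and 164 without GAUi A, B and C, and the 6 lists became 2 without control A.

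Whether the tRNA changes add up was tested as an interaction, the UAU effect in GAUi cells minus that in eGFP cells. In total RNA 3 of 12357 genes passed, with 1239 at an unadjusted p under 0.05. DESeq2 called 38, and the edgeR quasi-likelihood test called 95 with no count filter and 16 with all 36 libraries in a single fit. DDIT4 was at 112 ± 5.87 CPM in control, 61.2 ± 5.93 in UAU, 34.9 ± 3.61 in GAUi and 55.6 ± 2.65 in isoswitch (SD, n = 3; interaction 1.54 on the log2 scale, SE 0.14, adjusted p = 1.66e-05). INSIG1, at 294.4 CPM in control, 124.8 in UAU, 158 in GAUi and 134 in isoswitch, had an interaction of 1.00 (adjusted p = 0.000166, edgeR quasi-likelihood test). Control enters this contrast with a positive sign, so a high INSIG1 in the control cultures alone would give a positive interaction as well. SLC48A1, a haem transporter, had an interaction of -1.07 (adjusted p = 0.0174). Its call ended without control A (adjusted p = 0.0677), control B (0.107), control C (0.0995), isoswitch B (0.103), isoswitch C (0.0974), UAU A (0.0703) or UAU B (0.108). Cholesterol genes had positive interactions (1 of 22 called; 7 adjusted over the list alone; median 0.28; camera adjusted p = 2e-06; adjusted p = 0.026 with an estimated correlation). So had interferon response genes (0 of 24, and 0 adjusted over the list alone; median 0.37; camera adjusted p = 0.000422; adjusted p = 0.0389 with an estimated correlation). Mitotic genes passed camera (0 of 30; 1 adjusted over the list alone; adjusted p = 0.0117), but not with an estimated correlation (adjusted p = 0.673 with an estimated correlation). The count of 3 became 76, 44 and 11 without GAUi A, B and C.

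In the high-to-total ratio the interaction was broad: 2411 of 12540 genes passed, 1249 higher and 1162 lower, and 1601 without isoswitch A. ANXA1, a phospholipid-binding protein, had 72.6 ± 10.7 CPM in the high fraction of control and 37.5 ± 2.30 in that of UAU. It had 54.6 ± 6.17 in the high fraction of GAUi and 88.7 ± 16.95 in that of isoswitch. Its interaction in the ratio, which total RNA levels not given here also enter, was 2.07 (SE 0.26, adjusted p = 3.86e-06, edgeR quasi-likelihood test). FTO (2.20) and SCFD2 (2.23) also had positive interactions, and TRIAP1, a small apoptosis inhibitor, a negative one (-1.86). Mitotic genes (13 of 30 higher, 0 lower; 19 and 0 adjusted over the list alone), synthetases (11 of 20 higher, 0 lower; 11 and 0), replication genes (11 of 25 higher, 1 lower; 11 and 1) and glycolysis genes (8 of 23 higher, 0 lower; 8 and 1) had positive interactions. Ribosomal protein genes (3 of 78 higher, 37 lower; 3 and 46 adjusted over the list alone) and non-coding RNAs (0 of 20 higher, 9 lower; 0 and 10) had negative ones. Camera adjusted p values were 3.73e-06, 3.52e-06, 0.000186, 0.00173, 6.76e-11 and 6.28e-05 in this order. With an estimated correlation they were adjusted p = 0.179, 0.112, 0.112, 0.179, 0.112 and 0.179.

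The UAU effect was also compared between the backgrounds, in estimates that share no library. Its effect on the high-to-total ratio in eGFP cells and in GAUi cells had a Pearson correlation of -0.32 and a Spearman correlation of -0.43 across 12540 genes, with equal signs in 32.3% of them. With the filter of 50 counts in 3 libraries the Pearson correlation was -0.55 over 9896 genes. In the high fraction itself the Pearson correlation was -0.41 (Spearman -0.48), in total RNA 0.11 and in the low fraction -0.04. The effect of GAU CRISPR interference was compared between cells with and without UAU overexpression. It had a Pearson correlation of 0.42 in total RNA, 0.30 in the low and 0.01 in the high fraction (Spearman -0.14 in the high fraction). In the high-to-total ratio its Pearson correlation was -0.20 and its Spearman correlation -0.32, with equal signs in 36.5% of genes. These are correlations across genes, which are not independent replicates, so no p is given. RPS12 shows the contrast: in the high fraction it was at 1406 ± 121 CPM in control and 2099 ± 47.9 in UAU, but at 1788 ± 132 in GAUi and 1109 ± 155 in isoswitch.

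**Figure D4:**
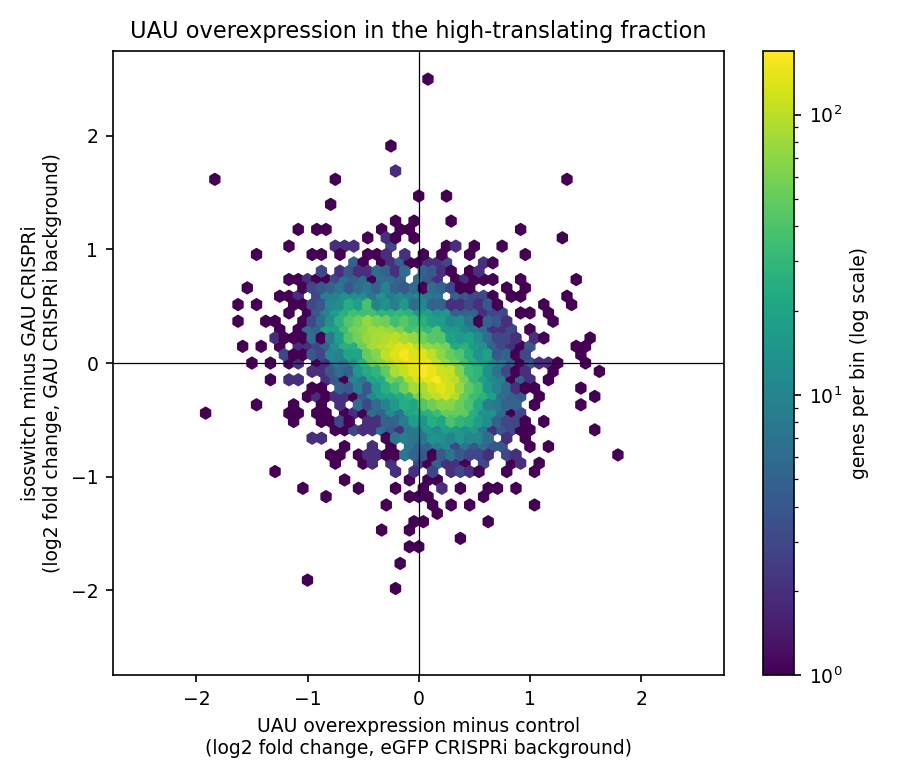
UAU effect in the high fraction as log2 fold change, in eGFP cells (UAU minus control, horizontal axis) and in GAUi cells (isoswitch minus GAUi, vertical axis); the colour gives the number of genes per bin on a log scale, and values beyond the axis limits are drawn at the edge. The cloud slopes downward, with a Pearson correlation of -0.41 across 11979 genes.

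Markers of other cell types were followed as a check, because the source label names a xenograft cell line. In control total RNA the 12 fibroblast markers summed to 14.5 ± 1.25 CPM, led by COL6A3. The 14 leukocyte markers summed to 102.4 ± 1.60 CPM, of which LAPTM5 alone gave 94.2 CPM. The 10 endothelial markers summed to 158 ± 5.70 CPM, of which ESAM gave 139.8 CPM. Luminal markers summed to 763 ± 18.8 CPM, led by the keratin KRT18. Luminal markers of the high fraction summed to 689 ± 26.5 CPM in control, 493 ± 58.6 in UAU, 545 ± 27.7 in GAUi and 733 ± 42.4 in isoswitch (SD, n = 3).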

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

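The S100A4 comparison of UAU with isoswitch libraries, the sterol comparison among the modified lines, the depth comparison for it, the comparison of low-fraction deviations and the direction of genes that separate isoswitch from GAUi were tests chosen only after the results were seen, and the interaction in the high fraction was not planned. The results here stand apart because the UAU effect differed between eGFP and GAUi cells in a test of the difference itself. In total RNA 3 genes passed: DDIT4 (1.54 on the log2 scale), INSIG1 (1.00) and SLC48A1 (-1.07). A positive interaction of INSIG1 could also come from a difference of the control cultures alone, which is left open below. In the high-to-total ratio 2411 passed, among them SCFD2 (2.23), FTO (2.20), ANXA1 (2.07), ANXA2P3 (2.04), MIR4458HG (-2.05), TERC (-2.01), HIST2H2AB (-1.87) and TRIAP1 (-1.86). In the high fraction 4276 passed, among them SDPR (1.79), FSCN1 (1.71), ALDH6A1 (1.68), ANXA2P3 (1.67), PKIA (-1.49), MYEOV2 (-1.48), SNRPG (-1.47) and TRIAP1 (-1.46). ANXA2P3 is a pseudogene of ANXA2 and HIST2H2AB a member of a gene family, so their reads are uncertain. TERC, at 2.00 to 4.23 CPM in the high fraction, lost its call without control B (adjusted p = 0.0503), UAU B (0.0621) or isoswitch A (0.074). The count of 2411 became 1601 without isoswitch A, and the count of 3 became 76, 44 and 11 without GAUi A, B and C. Of 30 regroupings of the libraries per interaction, the real one included, no other gave as many genes (1 of 30 each). The highest other count was 1 in total RNA (real 3), 0 in the high-to-total ratio (real 2411) and 0 in the high fraction (real 4276). The regroupings mixed libraries of all 4 lines, so differences between lines added to the spread within the regrouped groups. They ask whether the lines differ at all, and cannot exclude chance for the interaction alone.

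The UAU effect in the high fraction ran opposite ways in eGFP and GAUi cells (Pearson correlation -0.41 across genes). Exchanged UAU and isoswitch libraries are argued against by S100A4, whose lowest UAU library was 4.29 times the highest isoswitch library (CPM without TMM factors). Exchanged GAUi and isoswitch libraries cannot be told apart from a real effect: isoswitch minus GAUi correlated at only 0.034 between total RNA and high fraction, of 14 genes called in total RNA 5 had an equal sign and 9 the opposite sign in the high fraction, and of 6 called in both, 4 kept their direction (ID3, NDRG1, ZFP36L1 and DDIT4) and 2 turned (AP3D1 and OIP5-AS1). Separate handling of gradients, with control and isoswitch run apart from UAU and GAUi, also stays open. The interaction correlated at 0.12 between low and high fractions. It passed for 29 genes in the low and 4276 in the high fraction. That difference decides little, because splits mixing the lines outnumbered real calls for isoswitch and UAU in the low fraction. Unequal carry-over of light material stays open as well. In the high fraction, the UAU effect correlated with a low-minus-high profile at 0.163, and at -0.228 in GAUi cells. In the low fraction these correlations were 0.147 and -0.166. A biological explanation, that the UAU tRNA acts differently where the GAU tRNA is repressed, is what the design sets out to vary and may hold, but the tests at hand do not separate it from these.

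Cholesterol synthesis mRNAs were lower in all 3 modified lines than in control. In total RNA the modified libraries had on average 1.04 times the counts of control. The lowest of them had 0.908 times the counts of the highest control library. Levels were scaled to library totals, so these totals can neither give nor exclude a change of the list, and decide nothing about depth. A loss of RNA quality cannot be told apart from other causes. Of 10000 random lists of like expression 0% had a median as low as the list's -0.34 in isoswitch. The list was taken up for its low median, so this decides nothing. A difference of the control cultures alone, such as their sterol state at harvest, cannot be told apart from an effect of each construct, because the comparisons share control, and a biological effect of the tRNA changes stays open too. Over the 22 genes, the median was 0.068 for isoswitch minus UAU (camera adjusted p = 0.254) and -0.12 for isoswitch minus GAUi (camera adjusted p = 0.0239), a difference between modified lines that control alone would not give, but which did not hold (adjusted p = 0.247 with an estimated correlation).

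Control B of the low fraction stood apart from control A and C, with EPHA2 at 5.73 CPM against 66.0 and 58.7, and PLAU at 16.1 CPM against 110.3 and 105.5. Heavy material carried into this library is argued against, since its deviation correlated at 0.0053 with a high-minus-low profile. A source of variation that other low libraries carry too cannot be told apart from other differences: its deviation correlated at -0.34 with that of isoswitch B and -0.25 with that of UAU A, libraries picked from the splits given last, but at 0.21 with UAU C, 0.22 with isoswitch C and -0.088 to 0.13 with GAUi libraries, and at 0.29 with high-fraction control C. No biological explanation was tested, because the labels give these libraries no difference.

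In the comparisons of groups of 3, 10 splits of the libraries are too few for a share under 0.05. For the ratio and its interaction, high and total libraries of a line and letter were moved together, a pairing that no label gives. In that form, 1 split, the real one, was as large for the fractions in control (8094 genes, highest other 0), isoswitch (500 and 0), UAU (113 and 0) and GAUi (1248 and 1) in total RNA, isoswitch (1322 and 0), UAU (3432 and 0) and GAUi (1215 and 0) in the high fraction, the ratio in UAU (918 and 0) and GAUi (90 and 0), and GAUi in the low fraction (423 and 0). For the ratio in isoswitch all 10 splits gave 0 genes. For isoswitch in the low fraction 2 splits were as large (real 321, highest other 486), and for UAU in the low fraction 2 (real 86, highest other 293). The split with 486 genes put control A, control C and isoswitch B against control B, isoswitch A and isoswitch C, and that with 293 put control A, control C and UAU A against the rest. Those splits point to a structure of the low-fraction samples that the lines do not explain.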

How the results depend on the processing

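The alternatives for the low-fraction comparisons of UAU and GAUi, the interaction in the high fraction, the UAU effects within GAUi cells and part of the list alternatives were tests chosen only after the results were seen. The codon usage tests and their alternatives were not run. With RLE scaling all 18 counts of called genes stayed within 1.5 times, and the median over all genes moved by at most 0.015 (log2). The stricter count filter moved it by 0.11 in the comparison of fractions, the largest shift of any alternative. Of 5343 values of named genes under alternatives, 4784 kept direction and call, 442 lost the call, 95 gained one and 22 turned. For each result below that moved by over 1.5 times or turned, the cause was not tested.

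The direction turned in 22 values. Against total RNA in place of the low fraction, control cells gave ATP5B -0.13, KRT18 -0.52, KRT19 -0.14, LDHA -0.26 and ZBTB20 -0.11. Against the low fraction in place of total RNA, the ratio in GAUi gave HSPB1 0.15, PKM 0.0035, PLK1 0.19, QARS 0.048 and UBTD1 -0.067, and that in isoswitch gave IARS 0.16. IARS, which was called nowhere, turned in 11 fits with a replicate left out: in the fractions 0.034 without high control C and 0.032 without low control A (lowest -0.262), in GAUi high fraction 0.092 without control A and 0.0062 without GAUi C (lowest -0.153), in isoswitch high fraction -0.058 without control C, -0.0073 without isoswitch A and -0.037 without isoswitch C (highest 0.188), in isoswitch low fraction 0.017 without control A (lowest -0.27), in UAU low fraction -0.16 without control B and -0.066 without UAU A (highest 0.135), and in UAU total RNA -0.021 without UAU C (highest 0.138).

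With DESeq2 the interaction in total RNA had 38 genes, UAU 201 in total RNA and 209 in the low fraction, and the ratio in GAUi 262. With no count filter the interaction in total RNA had 95 genes, UAU 236 in total RNA and 339 in the low fraction, GAUi 743 and isoswitch 538 in the low fraction, and the ratio 278 in GAUi and 18 in isoswitch. With the stricter filter the interaction in total RNA had 5 genes, and with all 36 libraries in a single fit 16. Fits on the groups of the contrast alone gave, in total RNA, 1898 genes for isoswitch, 916 for UAU and 329 for GAUi; in the low fraction 105, 0 and 271; and in the ratio 15 for isoswitch, 1447 for UAU, 0 for GAUi and 330 for the UAU effect in GAUi cells. The counts of 0 compare with 86 and 90 by the edgeR quasi-likelihood test on all 4 lines, which had 1699 and 1853 genes at an unadjusted p under 0.05, and with 209 and 262 by DESeq2. Against the low fraction the ratio had 25 genes in GAUi and 1 in isoswitch, with 3 and 4 lists. The Pearson correlation of the UAU effect on the ratio was -0.55 with the stricter filter.

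With an estimated correlation, the lists that passed numbered 0 for the fractions; in total RNA 1 for isoswitch, 1 for UAU and 0 for GAUi; in the high fraction 0, 1 and 2; and 0 for each of the 3 ratios. With fry they numbered 12 for the fractions, 3 for isoswitch in total RNA, 3 for isoswitch and 6 for GAUi in the high fraction, and 0 for isoswitch and 1 for GAUi in the ratio.

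With 1 replicate left out, counts of called genes ranged from 194 to 268 for isoswitch, 25 to 43 for UAU and 531 to 2134 for GAUi in total RNA; from 651 to 1333 for isoswitch and 563 to 980 for GAUi in the high fraction; from 127 to 675, 6 to 209 and 177 to 760 for isoswitch, UAU and GAUi in the low fraction; and from 213 to 973 for UAU and 0 to 164 for GAUi in the ratio. They ranged from 2 to 76 for the interaction in total RNA, 1601 to 2741 for that in the ratio, 772 to 1839 for the UAU effect in GAUi cells in the high fraction and 99 to 1094 for it in the ratio. Lists that passed ranged from 2 to 5 for isoswitch, 2 to 4 for UAU in total RNA, 3 to 12 for GAUi in the high fraction, and 1 to 3, 6 to 13 and 2 to 6 for isoswitch, UAU and GAUi in the ratio.

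Replicate letters do not pair the samples by any label, and the block/pairing check found none: libraries of a line with the same letter in other fractions had a median correlation of their deviations of 0.017 over 36 pairs, and libraries of other lines in the same fraction 0.0047 over 54 pairs. With a replicate block, UAU in the low fraction had 22 genes. The other 17 counts stayed within 1.5 times, for example 436 for isoswitch in total RNA, 1260 in its high fraction and 2453 for the interaction in the ratio. The block was the letter, except in the ratio comparisons. There it was each line and letter, which pairs the high fraction with total RNA of the same letter, a pairing that no label gives.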

Other observations

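The low-fraction comparisons of UAU and GAUi with control, the comparisons of isoswitch with GAUi, of UAU with GAUi and of isoswitch with UAU, the interactions in the low and high fractions and the S100A4 comparison of UAU with isoswitch libraries were tests chosen only after the results were seen. In the low fraction, UAU cells carried the sterol change too: cholesterol genes were lower for 4 of 21 and higher for 0; adjusted over the list alone, 12 and 0 (median -0.44, camera adjusted p = 1.52e-10; adjusted p = 0.0012 with an estimated correlation). INSIG1 changed by -0.97 on the log2 scale. Immediate early genes had 1 of 20 higher and 0 lower; adjusted over the list alone, 3 and 0 (camera adjusted p = 8.27e-05; adjusted p = 0.183 with an estimated correlation). In total 86 genes were called, 41 higher and 45 lower (0 in a fit on the control and UAU libraries alone, edgeR quasi-likelihood test; 209 by DESeq2; 1699 at an unadjusted p under 0.05 in the fit of all 4 lines); the count was 23 without control A, 209 without control B, 40 without control C, 6 without UAU B and 22 without UAU C. In GAUi cells the low fraction had less S100A4 (-1.57, SE 0.13, adjusted p = 3.26e-06) and PRKAR1B (-1.69), and more CYR61, a matricellular protein (1.17, adjusted p = 0.00224). Interferon response genes were lower for 3 of 23 and higher for 0; adjusted over the list alone, 6 and 0 (median -0.28, camera adjusted p = 0.000101; adjusted p = 0.0178 with an estimated correlation). Cholesterol genes were lower for 3 of 21 and higher for 0; adjusted over the list alone, 3 and 0 (camera adjusted p = 0.00464; adjusted p = 0.0453 with an estimated correlation). In total 423 genes were called, 158 higher and 265 lower, and 271 in a fit on the control and GAUi libraries alone; the count was 760 without control B, 274 without control C, and 177, 194 and 178 without GAUi A, B and C.

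The effect of UAU overexpression on top of GAU CRISPR interference (isoswitch minus GAUi) was also read in the high fraction. Ribosomal protein genes were lower for 45 of 78 and higher for 1; adjusted over the list alone, 53 and 2 (median -0.25, camera adjusted p = 2.45e-16; adjusted p = 0.159 with an estimated correlation). Non-coding RNAs were lower for 15 of 19 and higher for 0; adjusted over the list alone, 15 and 0 (adjusted p = 0.159 with an estimated correlation). Mitotic genes were higher for 14 of 30 and lower for 0; adjusted over the list alone, 18 and 0 (adjusted p = 0.161 with an estimated correlation). Glycolysis and hypoxia genes were higher for 11 of 23 and lower for 0; adjusted over the list alone, 12 and 1 (adjusted p = 0.159 with an estimated correlation). In total 1897 genes were called, 788 higher and 1109 lower, and 994, 1158 and 772 without GAUi A, GAUi C and isoswitch A. In the high-to-total ratio 840 genes passed, 431 higher and 409 lower, and 99 and 321 without isoswitch A and isoswitch C. A fit on the GAUi and isoswitch libraries alone called 330. With the low fraction in place of total RNA 566 passed, 160 higher and 406 lower, and 226 of them were among the 840. By contrast, total RNA of isoswitch and GAUi differed in 14 genes and the low fraction in 0 (edgeR quasi-likelihood test; 890 at an unadjusted p under 0.05 in the low fraction).

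In the high fraction the ribosomal protein share was 15.8% in control and 15.7% in isoswitch, against 17.45% in UAU and 18.15% in GAUi. In genes called there, isoswitch and control differed in 1322 and UAU and GAUi in 2116, against 3432 for UAU and control, 1897 for isoswitch and GAUi, 1215 for GAUi and control and 4985 for isoswitch and UAU. The interaction, which sets control and isoswitch against UAU and GAUi, had 4276, and 29 in the low fraction. The spread of the low-fraction libraries may also give that lower count. In the high-to-total ratio isoswitch and control differed in 0 genes by the edgeR quasi-likelihood test (648 at an unadjusted p under 0.05) and in 0 by DESeq2. UAU and GAUi differed in 155, against 918 for UAU and control, 840 for isoswitch and GAUi and 90 for GAUi and control. Neither the high-fraction counts nor the ratio counts followed these pairs throughout. In both, GAUi and control, lines of different pairs, differed in fewer genes than UAU and GAUi. A candidate explanation is a difference between gradient runs shared by pairs of lines, which the correlation of 0.12 between the interactions of the low and the high fraction neither requires nor excludes. Sequencing or gradient dates for each library, or a repeat of the 4 lines in a single run, would test it.

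Another hypothesis is that loss of the GAU tRNA, rather than gain of the UAU tRNA, lowers S100A4, since its mRNA was at 208 and 283 CPM in the lines with GAU CRISPR interference and at 842 and 867 CPM in those without, and the lowest UAU library of the high fraction was 4.29 times the highest isoswitch library (CPM without TMM factors). A clonal difference between the GAU and eGFP lines could give the same values, because both lines with the GAU construct may descend from the same cells. An independent CRISPR interference guide, or restoring the tRNA in GAUi cells, would separate these.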
